A study of Arabidopsis thaliana with 12 samples.

How the data were processed

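Total RNA of the Arabidopsis thaliana toc120 mutant and of wild type (WT), both labelled with the Columbia 0 accession, was profiled on 12 arrays, 6 per genotype. Per the labels, the mutant is impaired in protein import across the outer envelope of the chloroplast. Tissue, plant age, growth conditions, array type and labelling are not given in the sources used here, and neither is whether the 6 samples of a genotype came from separate plants. The p-values therefore measure only the spread between these samples, which may be technical.

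The values used are the probe intensities the authors deposited, a single table of 3439 probes by 12 arrays on a linear scale that runs from 0 to 100. The background correction and scaling behind them are not given in the sources used here. On 7 arrays, all 6 of toc120 and WT 3, the brightest probe stood within 0.001 of 100, so the brightest values may be capped or scaled. On the other WT arrays it was at 67.7 to 99.4. Exact zeros made up 11.8% to 17.3% of an array's values. A probe at 0 is described only as listed at 0. The files hold no background or spot-level values, so no signal-to-background ratio could be given, and the number of arrays limits the precision.

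Probes were named from the GEO platform annotation, which can be out of date and was matched by locus against the TAIR10.1 gene table. Of the 3439 probes, 692 have 1 gene, 870 have several and 1877 have none. A locus was found for 690 of the 1-gene probes, giving 689 loci. Probes with several genes or none enter every count but are never named by gene. No coordinates are given, because the genome build behind the probes is not known.

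Choices made before the data were examined were the comparison, the test, the rule for scaling, the gene lists and the rule for naming genes. The scaling rule kept the intensities as deposited only if array totals or medians agreed within 10%. The highest total was 1.4 times the lowest, and the highest median 1.84 times the lowest, so the arrays were quantile-normalised. Values entered as log2(value + 0.0261), the added constant being the 5th percentile of the positive values, and fold changes are on that scale. The constant shrinks changes of dim probes. Where only part of a genotype's arrays are at 0, the fold can instead exceed the ratio of the mean levels. The toc120 and WT arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 3439 probes and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

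Within each genotype, arrays with neighbouring numbers (1 and 2, 3 and 4, 5 and 6) were more alike than other arrays, as duplicate readings would be, although the labels do not say so. A planned second fit averaged such neighbours first, leaving 3 pair means per genotype, and counts of calls are given with both fits. Levels are means ± SD of quantile-normalised intensity over those pair means (n = 3), and standard errors come from the averaged fit. Both fits were tested on simulated data with 3439 probes, 200 of them changed, in which neighbouring arrays were correlated as in the real ones, over 20 runs. The changed probes were drawn only from those above the lower quartile of mean level, so recovery was not measured for dimmer ones. With all 12 arrays, 30.7% of calls were false, and 52.2%, 79.3% and 96.3% of probes changed 1.5-, 2- and 4-fold were recovered. With neighbours averaged, 7.99% of calls were false, and 15.4%, 43.8% and 81.0% were recovered. In this simulation both false shares lay above the nominal 5%, and the averaged fit had the lower one. A false share depends on how many probes are changed, and far more than 200 were called in the real data. The simulation also had no correlation between equal numbers of the genotypes, which is described next. Its false shares therefore do not give those of the real calls.

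The genotypes share the numbers 1 to 6, and it was checked whether equal numbers pair the samples. Deviations from the genotype mean correlated between the toc120 and WT arrays of equal number with r from 0.22 to 0.35 across probes, and all 12 arrays correlated best, in the other genotype, with the array of their own number. The numbers thus appear to pair the samples, a pairing that comes from the data and not from the labels. Neither main fit used it, so p-values are unpaired unless a block is named. Fits with the number as a block, or the number pair after averaging, were run as alternatives.

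The 19 gene lists, of 351 loci, covered photosynthesis, chloroplast protein import, plastid ribosomes and other plastid functions, together with stress genes and cytosolic reference genes. Cytosolic ribosomal proteins and plastid-encoded genes had also been planned as lists, by description or locus prefix, and are not used here. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over those lists. Named genes are TOC120 and every measured chloroplast import gene, the 10 loci with the largest rise and the 10 with the largest fall among 1-gene probes past the threshold whose level exceeded the array median in at least 1 genotype, and the 2 members of each other list with the smallest p. Alternatives covered the scaling, the added constant, a filter on dim probes, each array left out, the pairing of numbers, array weights, the variance model and the set test.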

Results

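Expression was measured on 12 arrays, 6 of the toc120 mutant and 6 of WT. TOC120 is a receptor of the chloroplast outer envelope that takes part in the import of nucleus-encoded proteins, and the comparison asks which transcripts differ in level when it is mutated. The deposited intensities of an array summed to between 2641 and 3553 in WT and between 2688 and 3686 in toc120. Array medians were 0.151 to 0.157 in WT and 0.188 to 0.278 in toc120, so that before any scaling the typical probe was brighter in the mutant. The 10 brightest probes held 19.8% to 22.9% of an array's total in WT and 18.8% to 20.4% in toc120.

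The genotypes were clearly separate. Over all probes, Spearman's rho was 0.952 to 0.975 between neighbouring numbers of a genotype, 0.91 to 0.946 between its other arrays, and 0.806 to 0.859 between genotypes. These are correlations across probes, which are not independent replicates.

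**Figure D1:**
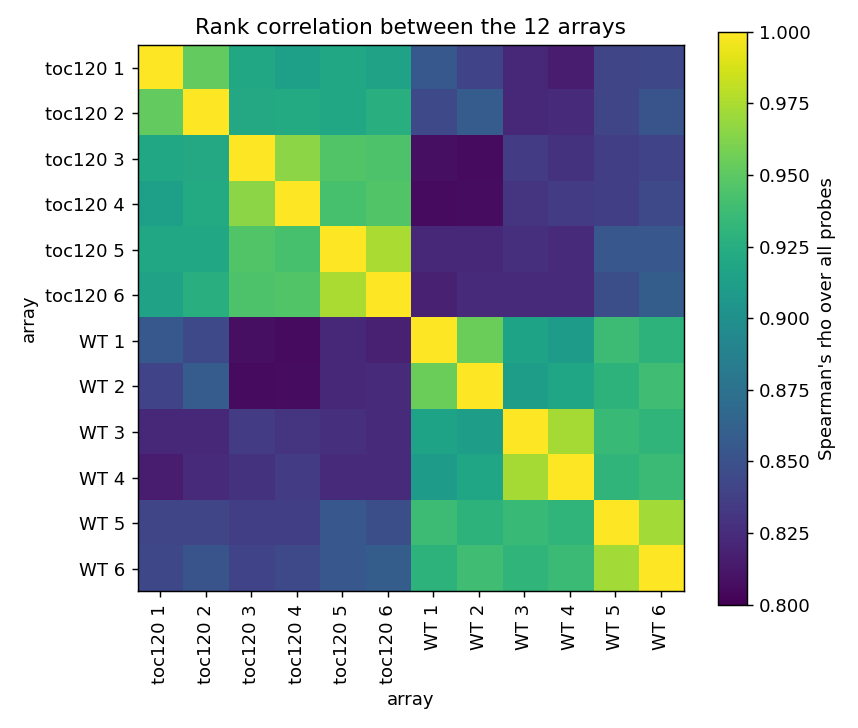
Spearman's rho over all 3439 probes for each pair of the 12 arrays, on a colour scale from 0.8 to 1. Arrays of a genotype form a block, neighbouring numbers within it are the most alike (0.952 to 0.975), and pairs of arrays from different genotypes lie between 0.806 and 0.859.

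The level of TOC120 itself could not be examined, because no 1-gene probe carries it. The same holds for the other members of the chloroplast protein import list, such as the remaining receptors and the channel proteins: 0 of its 27 loci had a 1-gene probe, and 1 lay on a probe shared by several genes. The genotype labels were therefore not checked against the mutated gene.

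Many transcripts differed between the genotypes, in both directions. XERICO, which encodes a RING-type zinc finger protein linked to abscisic acid metabolism, fell 7.61-fold, from an intensity of 2.742 ± 0.385 in WT to 0.3368 ± 0.0323 in toc120 (SD, n = 3 pair means each). AT4G32060, the gene of a mitochondrial calcium uptake protein, fell 4.45-fold, from 4.537 ± 0.516 to 0.9963 ± 0.0698. Among the rises, AT5G40030 went up 4.49-fold, from 0.6111 ± 0.1 to 2.814 ± 0.166, and AT1G74730 went up 5.19-fold, from 0.2258 ± 0.0183 to 1.296 ± 0.292. Genes of the glycosyl hydrolase 9 family, which holds plant endoglucanases, moved in opposite directions: GH9B16 rose 6.4-fold and GH9B12 fell 4.99-fold, with the caution that related family members may share signal on a probe. Folds of dim genes depend on the constant added before taking logs. With the median of the positive intensities, 0.24, in place of 0.0261, GH9B16 was up 1.78-fold and GH9B12 down 2.33-fold, against 5.14-fold for XERICO, 3.85-fold for AT4G32060, 3.6-fold for AT5G40030 and 3.26-fold for AT1G74730.

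Over the 12 arrays, 1587 of the 3439 probes passed the threshold (46.1%), 735 higher and 852 lower in toc120. With neighbouring numbers averaged, which leaves each log2 change as it is, 1084 passed, 503 higher and 581 lower. In both fits 1066 probes passed (494 higher, 572 lower). Of those, 621 differed more than 2-fold, 319 higher and 302 lower. Among probes with 1 gene, 321 passed over the 12 arrays (161 higher, 160 lower) and 210 in both fits (110 higher, 100 lower).

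The balance of rises and falls depended on the scaling. With the intensities as deposited, 1564 probes passed, 1164 of them higher and 400 lower, so that 74.4% of the calls were higher in toc120 against 46.3% after quantile normalisation. With neighbours averaged the deposited intensities gave 899 calls, 710 higher and 189 lower. With each array scaled to the same median, 656 probes were higher and 932 lower. The median log2 change of all probes was 0.23 as deposited, -0.04 with equal medians and 0 after quantile normalisation, and the changes below are relative to the last. Calls in a single direction under all 3 scalings and in both fits numbered 537, 360 higher and 177 lower, of which 108 (83 higher, 25 lower) were on 1-gene probes, while 16 probes were called in opposite directions under different scalings.

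**Figure D2:**
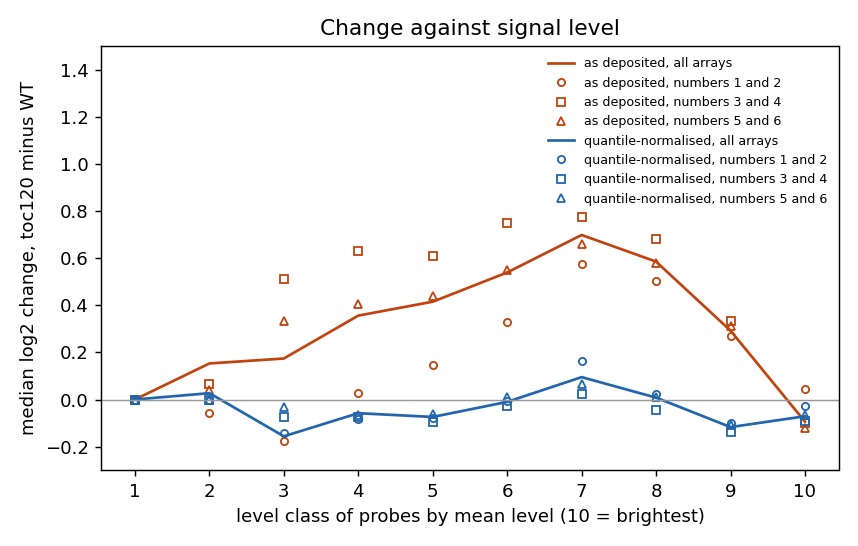
Median log2 change (toc120 minus WT, vertical axis) in 10 classes of probes ranked by mean level, 343 or 344 probes each (horizontal axis, 10 brightest), as deposited and after quantile normalisation. Lines are the 12-array values and open symbols the 3 pairs of neighbouring numbers. As deposited, the change reaches 0.70 in class 7 and -0.09 in class 10; the line after quantile normalisation stays between -0.16 and 0.10.

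Of the 10 genes with the largest rises, 8 passed in both fits and rose under all 3 scalings. AT1G62760 had the largest fitted rise of these 8 with the small constant, 7.82-fold, but not with the larger one (2.24-fold, below AT5G40030, AT1G74730, AT5G03370 and AT2G38500). It went from 0.03769 ± 0.00884 to 0.3779 ± 0.0454 (log2 change 2.97, SE 0.12, limma adjusted p = 0.00103 with neighbours averaged), although 3 of its 6 WT arrays were listed at 0. GH9B16, also listed at 0 on 3 WT arrays, had a log2 change of 2.68 (SE 0.31, limma adjusted p = 0.00431). AT5G40030 and AT5G03370, the latter up 3.95-fold, were measured above 0 on every array and had limma adjusted p-values of 0.00122 and 0.00114. The others were AT1G07040 (5.41-fold), which did not pass with neighbours averaged and the number pair as a block (limma adjusted p = 0.0538), AT1G74730 (5.19-fold), AT2G23890 (4.42-fold) and AT2G38500 (4.31-fold). With the larger constant, AT1G07040 was up 1.77-fold and AT2G23890 2.01-fold. With the small constant, AT4G21770 and AT2G27680 had the largest fitted values, 8.85-fold and 8.43-fold, and passed over the 12 arrays (limma adjusted p = 0.0101 and 0.0127). With the larger constant they were up 2.41-fold and 3.29-fold, below AT5G40030 at 3.6-fold. Their levels went from 0.146 ± 0.253 to 0.5883 ± 0.124 and from 0.2808 ± 0.27 to 1.254 ± 0.217, smaller rises than the small-constant folds. Neither passed with neighbours averaged (limma adjusted p = 0.134 and 0.125), and 4 and 2 of their WT arrays were listed at 0.

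Of the 10 genes with the largest falls, 9 passed in both fits and fell under all 3 scalings. AT4G12270 had the largest fitted value, 10.8-fold (2.62-fold with the larger constant, where XERICO was the largest), from 0.4537 ± 0.0592 to 0.02337 ± 0.0231 (n = 3 pair means), with 3 of its 6 toc120 arrays listed at 0. AT1G73120 fell 8.12-fold (limma adjusted p = 0.00833). XERICO had a log2 change of -2.93 (SE 0.13, limma adjusted p = 0.00103 with neighbours averaged and 3e-09 over the 12 arrays). AT4G32060 fell by 2.15 on the log2 scale (SE 0.11, limma adjusted p = 0.00109). PRA1.B3, a member of the prenylated Rab acceptor family, fell 4.62-fold and AT1G11730 3.92-fold. AT2G46300 fell 3.9-fold, and AT3G57630, which encodes an arabinosyltransferase acting on extensins, fell 3.62-fold from 0.2184 ± 0.0359 to 0.04094 ± 0.00487. With the larger constant the falls ranged down to 1.63-fold, for AT3G57630. AT1G24240, at 3.31-fold, did not pass with neighbours averaged (limma adjusted p = 0.0721), nor over the 12 arrays with the intensities as deposited (0.0647), but passed with neighbours averaged and the number pair as a block (0.0161).

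**Figure D3:**
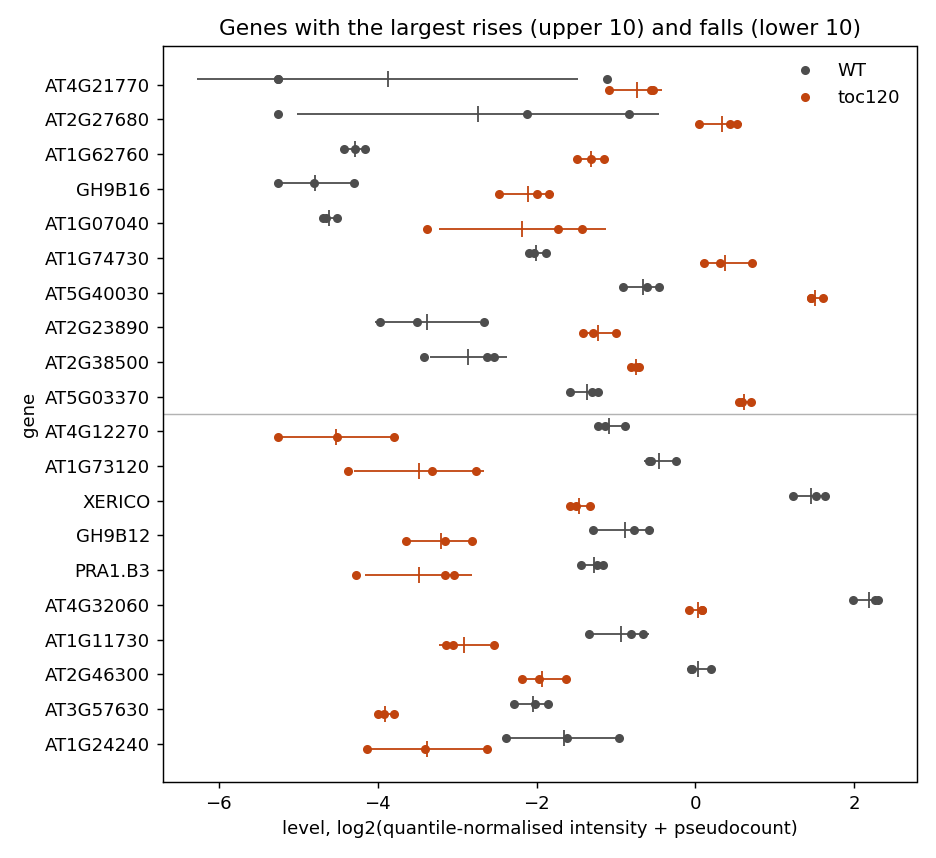
Level of the 10 genes with the largest rises (upper) and the 10 with the largest falls (lower), as log2 of quantile-normalised intensity plus the added constant (horizontal axis). Each point is the mean of a pair of neighbouring numbers, the tick is the mean of the 3 points and the bar is ± SD; XERICO falls by 2.93 and AT5G40030 rises by 2.17 on this scale.

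Nuclear genes of photosynthesis were thinly covered by 1-gene probes. Of the 77 loci on the 5 photosynthesis lists, 7 had such a probe and 6 lay only on probes shared by several genes. Whether others lie on the 1877 probes without a gene is not known. Of the photosystem II list, 3 of 13 loci were measured: PSBW and PSBY, which encode small photosystem II subunits, were lower over the 12 arrays and PSB27 did not pass (log2 change -0.38, limma adjusted p = 0.27). PSB27 passed with the sample number as a block (0.0158) and without numbers 1 and 2 (0.0204), but not with neighbours averaged and the number pair as a block (0.101), and was at 0.01 as deposited. PSBW was at 45.54 ± 5.41 in WT and 31.05 ± 8.14 in toc120, and PSBY at 3.138 ± 0.0596 and 2.511 ± 0.332 (SD, n = 3 pair means). With neighbours averaged, 0 of the 3 passed, the limma adjusted p being 0.145 for PSBW and 0.0801 for PSBY. The size of the difference depended on the scaling. PSBW was at -0.58 on the log2 scale after quantile normalisation, -0.86 as deposited and -1.46 with equal array medians, and under these last scalings it also passed with neighbours averaged (0.0254 and 0.0238). PSBY was at -0.33, -0.28 and -0.87, and as deposited it did not pass over the 12 arrays (0.0949). Adjusted over the list alone, 2 passed over the 12 arrays and 0 with neighbours averaged. The median log2 change of the list was -0.38, and camera did not call it (adjusted p = 0.35, and adjusted p = 0.401 with an estimated correlation). Fry, which asks only whether the members move 1 way on balance, gave an adjusted p of 0.000125 on the 12 arrays. It was not run with neighbours averaged.

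For the other photosynthesis genes too, size and call depended on the scaling. LHB1B2, a chlorophyll a/b binding protein of the light-harvesting antenna whose near-identical relatives may share its signal, was at 26.07 ± 1.86 in WT and 21.85 ± 1 in toc120, a log2 change of -0.25 that passed over the 12 arrays (limma adjusted p = 0.0228) but not with neighbours averaged (0.0634). It was at -0.48 as deposited, where it passed over the 12 arrays only (0.0285), and at -1.08 with equal array medians, where it passed in both fits (0.000303, and 0.0317 averaged). PRK, the Calvin cycle enzyme phosphoribulokinase, had a log2 change of -0.40 (limma adjusted p = 0.0232, and 0.0826 averaged). It was at -0.21 as deposited, where it did not pass (0.395), and at -0.80 with equal array medians (0.00384, and 0.0623 averaged). PSAN, a photosystem I subunit, had a log2 change of 0.36 (limma adjusted p = 0.0254, and 0.165 averaged), which did not pass as deposited (0.27) and turned to -0.37 with each array scaled to the same median (0.055). With the sample number as a block, PRK (0.0549) and PSAN (0.0736) did not pass. Their 12-array calls and that of LHB1B2 were also lost without particular arrays: PRK without WT 3 (0.0518), WT 5 (0.0507) or toc120 5 (0.0513), LHB1B2 without WT 3 (0.051) or WT 4 (0.05), and PSAN without any of WT 1 to 4 or toc120 4 (0.0512 to 0.0558). SBPASE, another Calvin cycle enzyme, was listed at 0 on all 6 WT arrays and on 3 toc120 arrays.

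The plastid ribosomal proteins did not move together. Of 6 measured members, AT5G65220 was higher (log2 change 0.68, limma adjusted p = 0.00257) and AT4G01310 lower (-0.49, limma adjusted p = 0.0263) over the 12 arrays, and 4 did not pass. Among these 4, AT1G64510 was listed at 0 on 5 WT and 3 toc120 arrays. With neighbours averaged, 0 of the 6 passed. AT5G65220 then had a limma adjusted p of 0.0666, but passed with the number pair as a block (0.0435) and as deposited (log2 change 1.22, 0.0414). Adjusted over the list alone the counts were 2 and 0. The fall of AT4G01310 became a value of 0.08 in the intensities as deposited, and the call was lost without WT 4, WT 5, WT 6 or toc120 4 (limma adjusted p from 0.0533 to 0.0573). Camera gave an adjusted p of 0.91 for the list, with the preset and with the estimated correlation alike.

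FATB, the acyl-ACP thioesterase that releases saturated fatty acids in the plastid, was the only one of the 19 measured members of the fixed lists to pass in both fits after quantile normalisation. Among all 692 probes with 1 gene, 210 passed in both fits, and the difference in share was not tested. FATB fell from 0.1824 ± 0.0485 to 0.06456 ± 0.018, a log2 change of -1.46 (SE 0.19, limma adjusted p = 0.00596 with neighbours averaged and 0.015 over the 12 arrays), which was -0.49 with the larger constant. The toc120 arrays disagreed: as deposited, toc120 3 was at 0.241, above all WT arrays (0.107 to 0.197), and its neighbour toc120 4 was listed at 0, so averaging them hides a large spread (SE 0.42 over the 12 arrays). FATB was lower under all 3 scalings but did not pass over the 12 arrays with the intensities as deposited (0.0963), nor with neighbouring numbers as a random block (0.146). The other fatty acid gene, AT1G24360, did not pass (log2 change 0.31), except as deposited (0.91, limma adjusted p = 0.00538). Of the redox genes, AT2G04700, a ferredoxin-thioredoxin reductase subunit, and NTRC, a plastid thioredoxin reductase, were lower over the 12 arrays (log2 changes -0.70 and -0.37, limma adjusted p = 0.0191 and 0.0281), did not pass with neighbours averaged (0.0751 and 0.203), and were at -0.15 and 0.18 as deposited, where neither passed (0.618 and 0.268). NTRC did not pass with equal array medians either (0.062). The call of AT2G04700 was lost with the sample number as a block (0.0692), and that of NTRC without WT 1, WT 2, toc120 3 or toc120 4 (0.056 to 0.0603). The chlorophyll synthesis genes CHLM (0.02) and AT1G74470 (-0.11) did not pass, except CHLM as deposited (0.60, limma adjusted p = 0.00123) and AT1G74470 with equal array medians (-0.82, limma adjusted p = 0.00219).

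In all, 19 of the 351 listed loci had a 1-gene probe, 11 of the 19 lists had no measured member, and only the photosystem II and plastid ribosomal lists reached the minimum of 3. Camera called 0 of these lists, and 0 had an unadjusted p under 0.05, whereas fry called 1. The lists without a measured member, among them protein import, isoprenoid synthesis, plastid proteases and chaperones, photorespiration, starch metabolism, stress genes and cytosolic reference genes, give no value for toc120.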

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

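Among the tests in this part, the 100 random splits, the comparison of level classes and the comparison of odd and even numbers were chosen after the results they bear on had been seen.

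Within WT, array 6 stood apart for AT2G23890, at a quantile-normalised intensity of 0.214 against 0.0168 to 0.079 on the other 5 WT arrays. The gap was 0.685 of the whole range, above Dixon's critical value for 6 samples. Without this array the log2 rise of AT2G23890 was 2.41 instead of 2.15 (limma adjusted p = 1.68e-05). By the same measure, toc120 3 stood apart for SBPASE, at 0.0343 against 0 to 0.0117 on the other toc120 arrays, and toc120 1 for AT1G62150, at 0.317 against 0.434 to 0.489. These were 3 of 98 groups of 6 arrays tested, and chance alone marks about 1 in 20.

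The number of calls was set against other groupings of the arrays. Of 100 splits of the 12 arrays into 6 and 6, 1, the real one, gave as many as 1587 calls, and the highest of the others gave 2. Of the 32 splits that separate the arrays of each number, 1, again the real one, gave as many, and the highest other gave 1. Both sets of splits exclude a random grouping only for arrays that vary independently, which the likeness of neighbouring numbers speaks against. With neighbours averaged there are only 10 splits, too few for a share under 0.05. There the real split gave 1084 calls, as many as in 1 of the 10, and the highest other gave 1. Every other split mixes the genotypes, so any strong difference between them widens the spread and leaves few calls. A consistent difference between the hybridisations of the genotypes would give the same outcome. The labels do not allow it to be told apart from the genotype, so the splits do not show that the mutation caused the calls.

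The excess of rises in the intensities as deposited was weighed first. If a scale factor per array were the whole cause, all well-measured probes would shift alike, but the median log2 change of level classes 7 and 8 of 10 exceeded that of class 10, the brightest, by 0.68 (0.485 to 0.836 over the 3 number pairs, SD 0.178). If a few bright probes set the scale, leaving out the 10 brightest would bring the share of rises near 50%, but it stayed at 68.8%. These probes held similar parts of the total in the genotypes (means of 21.2% in WT and 19.4% in toc120). Leaving them out and scaling to the remaining total could therefore change little, and the test cannot decide. Scaling each array to the same median, also a single factor per array, did remove the excess (41.3% of calls higher over the 12 arrays). A difference between the hybridisations of the genotypes may still be the source and cannot be told apart from the genotype, because 0 arrays have a label for filter, day or batch. The brightest probe was at 100 on every toc120 array but, in WT, only on array 3. A cap or scaling of the brightest values therefore cannot be told apart from the genotype either. A change in many transcripts of middling abundance in the mutant stays open as well, untested.

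The likeness of neighbouring numbers was weighed second. If each pair held duplicate readings of one hybridisation, for example at the 2 positions of a double-spotted filter, then arrays that are both odd or both even would share position effects across pairs. Their deviations correlated more than those of an odd with an even array by 0.1 on average (0.073 to 0.17), in 6 of 6 comparisons. Duplicate readings are thus a candidate explanation, found and tested on the same data. The 6 comparisons are not independent, because those within a genotype share arrays and equal numbers deviated together across genotypes. No biological explanation, such as material shared by neighbouring samples, was tested.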

How the results depend on the processing

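The fits that combine averaging with another choice, those without a pair of numbers, the filter on zeros, the median as added constant and the joined photosynthesis list were chosen after seeing the data; the other alternatives were planned. None of the 20 genes with the largest changes reversed under any alternative run. They were picked for large changes in the same data, which made a reversal unlikely in advance. Averaging on its own, the blocks and the variance model leave the log2 change as it is, so direction could not differ there. The count of 1587 changed probes moved to 899 with neighbours averaged and intensities as deposited, 912 with neighbours averaged and equal medians, and 979 with neighbours averaged and the number pair as replicate block. The 735 higher probes became 1164 with intensities as deposited, 370 with neighbours averaged and equal medians, and 482 with neighbours averaged and the pair block. The 852 lower probes became 400 as deposited, 189 as deposited with neighbours averaged, 542 averaged with equal medians, and 497 averaged with the pair block. Averaging leaves fewer samples in the fit; otherwise the cause was not tested. The number of lists called was 0 except with fry, run over the 12 arrays only, which gave 1. With the replicate block over 12 arrays 1688 probes were called (797 higher, 891 lower), 1505 of them among the 1587 in the same direction, and beyond the 4 genes given in the results (PSB27, PRK, PSAN, AT2G04700) the block changed no call of a named gene or list. With neighbours as a random block 1288 were called. Leaving out each array in turn gave 1506 to 1588 changed probes, 689 to 735 higher, 814 to 853 lower and 0 to 0 lists. Without numbers 1 and 2, 3 and 4, or 5 and 6 in both genotypes, 1524, 1290 and 1324 were called. Of the comparisons of the 20 genes with the largest changes, 574 kept direction and call and 19 kept direction but lost the call: 6 for AT4G21770, 5 for AT2G27680, 7 for AT1G24240 and 1 for AT1G07040 (adjusted p = 0.0538, averaged with the pair block). Of those of the 25 other genes named, 612 kept both, 113 lost the call, 5 gained it, 9 changed the sign of a value that passed in neither setting (CHLM, PSB27, GH9B11), and 6 reversed a called value: NTRC became 0.178 as deposited, PSAN -0.37 with equal medians and AT4G01310 0.076 as deposited, each in both fits, for which the cause was not tested. The level of TOC120 was planned under every alternative and was not run, for lack of a probe, and the list test with neighbours as a random block was not run. Signal over background is unknown, and 150 probes at 0 on all arrays could not show a change; the folds of dim genes shrank with the larger added constant, as its construction implies.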

Other observations

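The lists, genes and probes named in this part were chosen after their values had been seen; the test of the genes around TOC120 was planned before its result.

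Factors of organelle gene expression, most of them pentatricopeptide repeat or mTERF proteins that act on plastid or mitochondrial transcripts, moved in both directions. Of 14 measured, 2 rose and 3 fell with neighbours averaged, a fit that called 31.5% of all probes. Among those not called, AT3G22690 was listed at 0 on 6 WT and 5 toc120 arrays, and OTP85 on 5 and 4. CRR21, an editing factor of a plastid ndh transcript, rose from 0.2712 ± 0.0166 to 0.6471 ± 0.141 (SD, n = 3 pair means; log2 change 1.16, SE 0.17, limma adjusted p = 0.00897), and AT1G79220 rose from 0.1197 ± 0.0157 to 0.4303 ± 0.119 (log2 change 1.70, limma adjusted p = 0.00617). OTP70, a factor of plastid splicing, fell from 1.161 ± 0.325 to 0.3401 ± 0.0547 (log2 change -1.67, SE 0.23, limma adjusted p = 0.00678). These 3 genes were called in their direction under all 3 scalings. With the median intensity as added constant they were at 0.78, 0.89 and -1.25. AT1G61990 (-0.71) and AT1G62150 (-0.85) were lower under all 3 scalings but did not pass with the intensities as deposited (limma adjusted p = 0.3 and 0.0954). Camera did not call the group (adjusted p = 0.952, and adjusted p = 0.958 with an estimated correlation), and fry gave 0.276.

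Of 8 NDH complex and photosystem assembly factors, 1 was higher and 2 lower over the 12 arrays, a fit that called 46.1% of all probes. CRR41 and AT1G49380 were listed at 0 on all 12 arrays and could not show a change. NdhN was listed at 0 on 3 WT and 5 toc120 arrays. All stayed in the list test. LPA19, which assists photosystem II assembly, fell in both fits, from 0.2309 ± 0.0299 to 0.08983 ± 0.0305 (log2 change -1.21, limma adjusted p = 0.0171 with neighbours averaged, but 0.0717 with these averaged as deposited). CCB3, a cytochrome b6f assembly factor, had a log2 change of 1.03 (limma adjusted p = 0.0058, and 0.0535 averaged). With the median intensity as added constant LPA19 was at -0.52 and CCB3 at 0.38. NdhS had a log2 change of -0.17 (0.0443, and 0.204 averaged), a call also lost without any 1 of 8 arrays, WT 1 to 4, WT 6, toc120 3, toc120 5 or toc120 6 (0.0604 to 0.0899). Camera gave the list an adjusted p of 0.807 (0.857 with an estimated correlation). The 5 photosynthesis lists joined had 7 measured members, 1 higher and 4 lower over the 12 arrays and 0 called with neighbours averaged. The shares over all probes were 46.1% and 31.5% in these fits. Over the 12 arrays, camera gave an adjusted p of 0.807 (0.857 with an estimated correlation) and fry 0.0093. Fry was not run with neighbours averaged. In the glycosyl hydrolase 9 family, GH9B8 had a log2 change of 1.17 that passed over the 12 arrays (limma adjusted p = 0.0125) and not with neighbours averaged (0.094), though it did with these as deposited (1.51, limma adjusted p = 0.0449). Without numbers 5 and 6 it was at 0.66 and did not pass (0.129), and with the median intensity as added constant it was at 0.27. GH9B11 did not pass in either fit (-0.29, and 0.10 as deposited).

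At the extremes of the scale, 124 probes were listed at 0 on all WT arrays and not on all toc120 arrays, 12 of them called higher, and 58 were listed at 0 on all toc120 arrays only, 2 of them called lower. Probe 3499, which has no gene name, was at 100 on all 6 toc120 arrays and at 62.5 to 98.3 on the WT arrays in the intensities as deposited. After quantile normalisation it did not pass (limma adjusted p = 0.137 over the 12 arrays and 0.374 with neighbours averaged). Probe 4360, which carries several genes, went from 25.54 ± 11 to 64.99 in toc120 (log2 change 1.46, limma adjusted p = 0.0457 with neighbours averaged).

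A segment of chromosome around the mutated gene could differ between the lines if the mutant kept flanking sequence of another origin, and would then hold more changed genes than elsewhere. Among the 20 measured loci nearest TOC120, 4 were called with neighbours averaged (20%), against 211 of 669 others (31.5%), an odds ratio of 0.543 (95% interval 0.131 to 1.71, Fisher's exact test, two-sided, p = 0.335). Over the 12 arrays the numbers were 8 of 20 and 313 of 669 (Fisher's exact p = 0.652). With 20 loci the interval spans 1, so the hypothesis is neither borne out nor excluded.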
